A study of Kluyveromyces lactis with 8 samples.

How the data were processed

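RNA was measured in 8 libraries of the milk yeast Kluyveromyces lactis, in 4 groups of 2 libraries: a wild-type strain (WT) and strains lacking SIR2, SIR4 or SUM1. Per the labels' protocols, all strains were of mating type a with the silent mating cassettes HML and HMR deleted. Cells grew at 30 °C in rich glucose medium (YPD) from a starting OD of 0.3 to a harvest OD of 1. Total RNA was extracted with hot phenol and treated with DNase, and libraries were made with a kit that does not keep the strand and read as single 50-base reads. The series design calls the members of each group technical replicates. The p-values therefore measure only the spread between these libraries, which may be technical, and do not cover variation between cultures.

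The deposited values are FPKM (fragments per kilobase of gene per M fragments), given by the authors for 5076 genes in each library. TopHat2 2.0.10 and Cuffnorm 2.2.1 are the tools named in the submitters' processing notes. The genome build and the annotation are not given in the sources used here. Because strand was not kept, reads of a gene cannot be told from reads of an overlapping or antisense neighbour, and close paralogs may share reads.

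All 5076 identifiers matched the locus tags of the reference gene table (assembly ASM251v1), which gave a symbol to 3959 of them. The table was used only for symbols and for the order of genes along chromosomes, and no coordinates are given because the authors' build is not named. It holds no entry with the symbol SIR2 or SIR4, so these deletions could not be checked by symbol. Of the lengths listed there, 97.8% are multiples of 3, so lengths are coding lengths. Values of short genes such as AGA2, STE18 and FMP16, each with a coding length of 273 bases, depend more on the length correction than those of long genes.

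Depth was estimated from the steps between low FPKM values, since each read adds a fixed amount to a gene of given length. The effective length assumed a fragment mean of 200 and an SD of 80 bases. Low genes, with at most 100 reads and a coding length over 600 bases, came out as whole reads within a tolerance of 0.1 in 95.7% to 100% of cases per library. The estimated reads assigned to genes were 21.7 and 11.8 M in WT, 10.1 and 21.2 M in sir2∆, 10.6 and 11.5 M in sir4∆, and 21.7 and 26.2 M in sum1∆. The libraries fell into a shallow class (WT replicate 2, sir2∆ replicate 1 and both sir4∆ libraries) and a deep class (WT replicate 1, sir2∆ replicate 2 and both sum1∆ libraries). This depth class was defined from the data and overlaps with the sir4∆ and sum1∆ groups. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 18.5 in WT, 9.53 in sir2∆, 8.14 in sir4∆ and 4.74 in sum1∆. Separate preparation of libraries from the same RNA could also give this, so it does not show separate cultures.

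Genes with a mean of at least 1 FPKM over the 8 libraries were tested (5022 genes). The tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and all 4 groups sharing an estimate of the spread (4 residual and 4.02 prior degrees of freedom). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. The comparisons were each mutant against WT and each pair of mutants. Count models were not used because the values are FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.

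There were 22 gene lists, fixed before the data were examined: silencing factors, early meiosis, middle and late sporulation, a-specific, alpha-specific, haploid and pheromone response, NAD metabolism, galactose and lactose, sugar transport, iron and siderophores, phosphate, cell wall and adhesion, stress response, multidrug export, amino acid uptake, amino acid synthesis, selectable markers, glycolysis and fermentation, TCA cycle and respiration, histones, ribosomal proteins and ribosome biogenesis. Names were matched by symbol. Lists with at least 3 tested members were tested with camera (preset correlation of 0.01), again with an estimated correlation, and with fry, and 21 lists qualified. The ribosomal protein list was matched by name pattern and also takes in RPP1, a subunit of RNase P. Chromosome-end genes were the outermost 10 annotated protein-coding genes at each of the 12 ends of the 6 chromosomes, compared with other genes by a 2-sided Fisher's exact test. Overlaps between mutants were set beside the product expected of independent lists. Overlaps and correlations were also set beside 100 simulations of unchanged groups sharing the WT libraries. Genes next to each other were counted against 10000 random assignments of the calls.

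The genes named were chosen by a rule set before the data were examined. For each mutant against WT it took SIR2, SIR4 and SUM1, the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. It added up to 4 called members of each list, up to 2 members of a list with no call, and at most 2 genes without a symbol per direction. Between mutants it took 5 genes per direction.

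The model was tested on simulated data for the sir2∆ comparison over 5022 genes. It called 50 of 50 genes raised 3-fold, 50 of 50 raised 6-fold and 49 of 50 lowered to 0.333 of their level, none of 50 raised 1.5-fold (48 of which had an adjusted p below the threshold), and 0 of 4822 unchanged genes. The depth estimate and the count of neighbours were also tested on simulated data. Alternatives tried were other pseudocounts, filters, scalings, priors and thresholds, a fit of only the groups compared, a replicate block and the removal of each library in turn. A term for depth class and a different control for sum1∆ were added after seeing the data.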

Results

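Transcript levels were measured in WT K. lactis and in strains lacking SIR2, which encodes an NAD-dependent deacetylase, SIR4, which encodes a silencing protein, or SUM1, which encodes a DNA-binding repressor. Each group held 2 libraries, described in the series design as technical replicates. The estimated reads assigned to genes ranged from 10.1 to 26.2 M per library, and 5022 of 5076 genes were tested. The deleted genes were examined first. SUM1 was listed at 0 in both sum1∆ libraries and at 31.2 and 28.0 FPKM in the WT libraries. It stood at 56.6 and 59.8 FPKM in sir2∆ and 22.1 and 24.6 FPKM in sir4∆. No identifier carried the symbol SIR2 or SIR4. KLLA0F14663g, which has no symbol, was the 1 gene below 0.1 FPKM in both sir2∆ libraries and at 10 FPKM or more in the other 6 libraries, with 0.0257 ± 0.0363 FPKM in sir2∆ and 72.1 ± 1.53 FPKM in WT (mean ± SD, n = 2). It was singled out after its values were seen. No gene met that criterion for sir4∆, so the sir4∆ label could not be checked in this way.

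**Figure D1:**
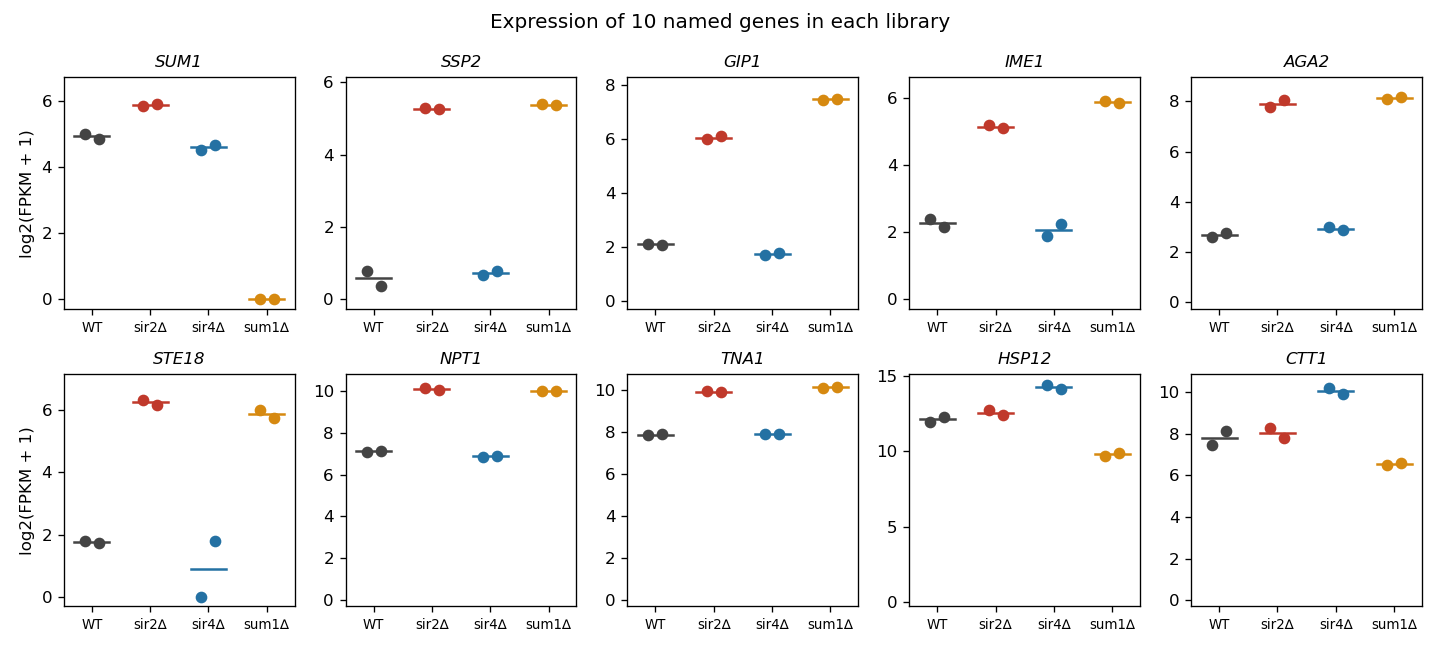
Expression of 10 named genes as log2(FPKM + 1) on the vertical axis in WT, sir2∆, sir4∆ and sum1∆, with points for the 2 libraries of a group and a line at their mean. SSP2, GIP1, IME1, AGA2, STE18, NPT1 and TNA1 are higher in sir2∆ and sum1∆ than in WT, and HSP12 and CTT1 are higher in sir4∆.

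The comparison of sir2∆ with WT asked which transcripts depend on Sir2. Among genes with a symbol, the largest rises included genes of sporulation and mating. SSP2, needed for spore wall formation, rose from 0.488 ± 0.299 to 37.7 ± 0.213 FPKM (mean ± SD, n = 2, log2 fold change 4.72, SE 0.14, adjusted p = 7.9e-08). GIP1, a sporulation-specific regulator of the phosphatase Glc7, rose from 3.28 ± 0.0985 to 65.3 ± 3.80 FPKM. AGA2, the binding subunit of a-agglutinin, rose from 5.37 ± 0.541 to 240 ± 30.9 FPKM (log2 fold change 5.24, SE 0.10, adjusted p = 1.14e-08). In all, 246 genes were called higher and 36 lower, so 87.2% of calls were rises. With quantile normalization the share of rises was 68.3%. Without the fold threshold 1452 and 1465 genes were higher and lower, so the excess of rises holds for changes past that threshold.

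In the middle and late sporulation list 23 of 37 tested genes rose and none fell (23 adjusted over the list alone), with a median log2 fold change of 1.53, or 1.01 with quantile normalization. Camera gave an adjusted p of 1.8e-12, and the adjusted p = 0.0216 with an estimated correlation. Besides SSP2 and GIP1, the log2 fold changes were 3.96 for CRR1 and 4.42 for MUM3, both of which act in spore wall assembly. PFS1 and RRT8 rose by 4.62 and 4.46. In the early meiosis list 7 of 25 genes rose and none fell (7 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.148 with an estimated correlation). IME1, the activator of meiotic entry, rose from 3.88 ± 0.595 to 34.6 ± 1.47 FPKM, and NDJ1, MND1 and SPO11, which act at meiotic telomeres and in recombination, rose by 2.57, 2.37 and 1.91 on the log2 scale. SPO11 stayed low, at 3.43 ± 1.18 FPKM, and lost its call with a pseudocount of 5 (log2 fold change 0.70) and with quantile normalization (0.75). The median of this list was 0.38, also with median-ratio scaling, and turned to -0.10 with quantile normalization. Quantile normalization moved the median of all genes in this comparison from -0.01 to -0.08.

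Of 6 a-specific genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.00807, adjusted p = 0.342 with an estimated correlation). These were AGA2, BAR1, which encodes the protease that degrades alpha factor (3.68), and ASG7 (1.16), whose call was lost with a pseudocount of 5 (0.78) and with quantile normalization (0.48). None of the 3 tested alpha-specific genes was called (camera adjusted p = 0.895), with STE3 at -0.19 and AFB1 at 0.20. Among haploid and pheromone response genes 6 of 24 rose (6 adjusted over the list alone, camera adjusted p = 0.0557), including the G protein subunits STE18 (4.49) and GPA1 (1.94), PRM1 (2.47) and KAR4 (1.65). The median of that list was 0.21, also with median-ratio scaling, and turned to -0.04 with quantile normalization.

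In the NAD metabolism list 2 of 10 genes rose (2 adjusted over the list alone). NPT1, which makes nicotinic acid mononucleotide, rose from 137 ± 4.36 to 1085 ± 56.3 FPKM (log2 fold change 2.97, SE 0.06, adjusted p = 1.02e-08), and TNA1, the nicotinic acid permease, rose from 229 ± 6.58 to 951 ± 14.2 FPKM (log2 fold change 2.05, SE 0.05, adjusted p = 1.93e-08). The list as a whole did not pass with camera (adjusted p = 0.519) but passed with fry (adjusted p = 0.000458). Its median of -0.02 and mean of 0.46 differed in sign. Of 57 ribosomal protein genes 1 fell, RPL9B (log2 fold change -1.35), and the list was lower with a median of -0.32 (camera adjusted p = 2.04e-12, adjusted p = 0.342 with an estimated correlation). That median was -0.13 with quantile normalization. None of 72 ribosome biogenesis genes was called, and that list was higher with a median of 0.24, or 0.16 with quantile normalization (camera adjusted p = 0.00807, adjusted p = 0.846 with an estimated correlation). IMP4, RRP3, MAK5 and SPB1 stood at 0.75, 0.61, 0.57 and 0.37.

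Other rises in sir2∆ were MET14, an enzyme of sulfate assimilation (3.16, 1 of 47 amino acid synthesis genes), SPL2 (1.93, 1 of 7 phosphate genes), ICL1, isocitrate lyase (1.71, 1 of 18 glycolysis and fermentation genes), PHO92 (4.27) and MOH1 (4.04). KLLA0F24596g and KLLA0C17226g, without symbols, rose by 7.28 and 6.18. The largest falls of genes with a symbol were STE23 (-1.76), the sterol synthesis genes ERG1 (-1.70) and ERG11 (-1.34), the peptide permease PTR2 (-1.62, 1 of 17 amino acid uptake genes), SUR2 (-1.57), RPL9B, LSC2 (-1.34, 1 of 37 TCA cycle and respiration genes), URA1 (-1.33, 1 of 10 selectable markers), SPG4 (-1.33) and GAL7 (-1.26, 1 of 6 galactose and lactose genes). FIT2 fell by 1.18 on the log2 scale (1 of 13 iron genes). KLLA0E05897g fell by 2.14. Camera did not pass the threshold for these lists (adjusted p between 0.0544 and 0.806), though with depth class as a term amino acid uptake (adjusted p = 0.0419) and glycolysis and fermentation (adjusted p = 0.0342) did. That term left the medians of these 2 lists at -0.197 and -0.435. WT and sir2∆ each hold both depth classes, so the term could not change these medians, whatever the depth effect. Without the term, camera with an estimated correlation gave these 2 lists an adjusted p of 0.4 and 0.406. No member was called among 10 silencing factors, 12 cell wall, 22 stress response, 10 multidrug export or 10 histone genes (camera adjusted p between 0.0808 and 0.509). SUM1 was 58.2 ± 2.28 FPKM in sir2∆ against 29.6 ± 2.27 FPKM in WT, with a log2 fold change of 0.95 that missed the fold threshold and reached 1.03 without WT replicate 1. The 2 genes found of the sugar transport list, too few for a list test, were not called.

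The comparison of sir4∆ with WT asked the same of Sir4. Among genes with a symbol, CTT1 and HSP12 of the stress response list rose most. HSP12, a small membrane heat shock protein, rose from 4557 ± 724 to 20115 ± 2154 FPKM (mean ± SD, n = 2, log2 fold change 2.15, SE 0.14, adjusted p = 0.000403), and CTT1, the cytosolic catalase, rose from 227 ± 72.3 to 1054 ± 146 FPKM (log2 fold change 2.24, SE 0.22, adjusted p = 0.000725). SFC1, the mitochondrial succinate and fumarate carrier, fell from 111 ± 24.4 to 32.6 ± 0.971 FPKM (log2 fold change -1.73, SE 0.13, adjusted p = 0.000564). In all, 31 genes were called higher and 37 lower. These counts depended on single libraries: 17 and 20 without WT replicate 1, 70 and 62 without WT replicate 2, and 49 and 64 without sir4∆ replicate 2. With depth class as a term, an alternative chosen after seeing the data, 19 and 26 genes were called, all of them among the 31 and 37. With limma's treat against a log2 fold of 1, a stricter test by construction, 0 and 0 were called.

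In the stress response list 4 of 22 genes rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.73 with an estimated correlation): HSP12, CTT1, MSC1 (1.72) and the aldose reductase GRE3 (1.48). ARA1 (2.13), FMP16 (2.06), RTC3 (1.22) and OM45 (1.15) also rose, as did the sterol synthesis genes ERG3 (1.52) and ERG11 (1.11, 0.92 and not called without WT replicate 1). KLLA0F20900g and KLLA0C19338g rose by 2.07 and 2.01. Other falls were the carbonic anhydrase NCE103 (-1.49), the aldehyde dehydrogenases ALD5 (-1.48) and ALD6 (-1.31, both among 18 glycolysis and fermentation genes), SUT1 (-1.31), the copper transporter CTR1 (-1.27), SPL2 (-1.19, 1 of 7 phosphate genes), ARO10 (-1.11), FRE1 (-1.10, 1 of 13 iron genes) and DTR1 (-1.02, 1 of 10 multidrug export genes). The calls of SUT1, ARO10, FRE1 and DTR1 were lost without WT replicate 1 (-0.92, -0.98, -0.90 and -0.88), and those of CTR1, ARO10 and DTR1 without sir4∆ replicate 1 (-0.95, -0.99 and -0.75). The DTR1 call was also lost with a pseudocount of 5 (-0.95) and with quantile normalization (-0.97). KLLA0E24861g fell by 2.27. KLLA0E16149g was listed at 0 in both sir4∆ libraries and at 3.44 and 44.5 FPKM in the WT libraries, and its call was lost without sir4∆ replicate 1 (adjusted p = 0.0543).

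Of 72 ribosome biogenesis genes 3 fell (3 adjusted over the list alone), RRP1 (-1.12) among them, and the list was lower with a median of -0.54 (camera adjusted p = 2.53e-17, adjusted p = 0.73 with an estimated correlation). DIM1, outside this list, fell by 1.12. Without WT replicate 1 neither DIM1 (-0.98) nor RRP1 (-0.89) was called, and DIM1 was not called without sir4∆ replicate 1 (-0.99). The TCA cycle and respiration list was lower with a median of -0.37 and 1 of 37 genes called (camera adjusted p = 6.24e-13, adjusted p = 0.699 with an estimated correlation), with ACO1 at -0.62 and FUM1 at -0.49. Ribosomal proteins (median -0.08, camera adjusted p = 0.00373), amino acid uptake (median 0.25, adjusted p = 0.0138) and NAD metabolism (median 0.20, adjusted p = 0.0451) passed with no gene called. Of these, ribosomal proteins and NAD metabolism had an adjusted p = 0.73 with an estimated correlation and amino acid uptake an adjusted p = 0.699 with an estimated correlation. With depth class as a term the medians were -0.44 for ribosome biogenesis, -0.34 for TCA cycle and respiration and 0.23 for stress response, and NAD metabolism lost its call (adjusted p = 0.0602).

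No gene of the sporulation, meiosis or mating lists was called higher in sir4∆. Of 37 middle and late sporulation genes none rose and 2 fell (2 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.962, median 0.06 with quantile normalization). These were PFS1, from 4.65 ± 0.210 to 1.82 ± 0.324 FPKM, and DTR1, whose call was lost under several settings above. The lowest log2 fold change of the list was -1.02, so both falls were just past the fold threshold. No gene was called among 25 early meiosis genes (adjusted p = 0.917), 6 a-specific genes (0.54), 3 alpha-specific genes (0.107) or 24 haploid genes (0.746). The medians of early meiosis and haploid genes, both -0.01, were 0.06 and 0.04 with quantile normalization. STE18 was called lower without sir4∆ replicate 2 (-1.76) but stood at 0.04 without sir4∆ replicate 1, and the marker gene URA1 was called higher without WT replicate 2 (1.06). SSP2 stood at 0.630 ± 0.0986 FPKM, IME1 at 3.24 ± 0.729 FPKM, AGA2 at 6.60 ± 0.532 FPKM, NPT1 at 116 ± 3.33 FPKM and TNA1 at 234 ± 0.359 FPKM. No gene was called among silencing factors, galactose and lactose, sugar transport, cell wall, amino acid synthesis, selectable marker or histone genes, and camera gave an adjusted p between 0.0668 and 0.866 for the remaining lists tested, those on iron, phosphate, multidrug export and glycolysis included.

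The comparison of sum1∆ with WT asked which transcripts depend on Sum1. Among genes with a symbol, the largest rises included AGA2 and the sporulation genes MUM3 and GIP1, and ALD4 fell most after SUM1. MUM3 rose from 1.56 ± 0.527 to 110 ± 1.75 FPKM (mean ± SD, n = 2, log2 fold change 5.45, SE 0.18, adjusted p = 1.12e-07), and GIP1 rose from 3.28 ± 0.0985 to 175 ± 5.52 FPKM (log2 fold change 5.36, SE 0.07, adjusted p = 3.29e-09). ALD4, a mitochondrial aldehyde dehydrogenase, fell from 72.9 ± 2.95 to 6.23 ± 0.400 FPKM (log2 fold change -3.36, SE 0.11, adjusted p = 8.51e-08). In all, 388 genes were called higher and 144 lower, 72.9% of calls being rises, against 61.1% with quantile normalization. Without the fold threshold 1689 and 1635 genes were higher and lower. Both sum1∆ libraries are in the deep class. With depth class as a term, an alternative chosen after seeing the data, 353 and 128 genes were called, 348 and 126 of them among the 388 and 144.

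In the middle and late sporulation list 26 of 37 genes rose and none fell (26 adjusted over the list alone), with a median of 1.89, or 1.46 with quantile normalization (camera adjusted p = 2.35e-11, adjusted p = 0.0273 with an estimated correlation). CRR1, SSP2 and SPR3, a septin of sporulation, rose by 4.87, 4.83 and 4.71, and RRT8 and PFS1 by 4.78 and 4.49. Of 25 early meiosis genes 9 rose (9 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.271 with an estimated correlation), with IME1 at 3.62, NDJ1 at 3.12, MND1 at 2.09 and SPO11 at 1.22. The SPO11 call was lost with a pseudocount of 5 (0.38) and with quantile normalization (0.58), and the list median of 0.15 turned to -0.11 with quantile normalization. With median-ratio scaling that median stayed at 0.15. Of 6 a-specific genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.421 with an estimated correlation): AGA2 (5.47), BAR1 (4.04) and ASG7 (1.03), the last losing its call without WT replicate 1 (0.89) or sum1∆ replicate 1 (0.82), with a pseudocount of 5 (0.69) and with quantile normalization (0.40). None of 3 alpha-specific genes was called (camera adjusted p = 0.381, median 0.22, also with median-ratio scaling, or -0.11 with quantile normalization). Of 24 haploid and pheromone genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.114), with STE18 at 4.11, PRM1 at 3.44, KAR4 rising from 7.87 ± 0.109 to 70.3 ± 7.12 FPKM and GPA1 at 2.24, and the list median of 0.16 turned to -0.09 with quantile normalization. With median-ratio scaling the haploid median was 0.165.

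NPT1 rose from 137 ± 4.36 to 1028 ± 2.40 FPKM and TNA1 from 229 ± 6.58 to 1096 ± 14.7 FPKM, 2 of 10 NAD metabolism genes (2 adjusted over the list alone, camera adjusted p = 0.875, median -0.07, mean 0.41). That list passed with fry (adjusted p = 0.000389). Of 72 ribosome biogenesis genes 26 rose and none fell (26 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 1.18e-12, adjusted p = 0.527 with an estimated correlation); RRP3, MAK5, SPB1 and IMP4 stood at 1.58, 1.36, 1.36 and 1.31. Ribosomal proteins were lower with a median of -0.32 and 1 of 57 called, RPL9B (-1.19, camera adjusted p = 8.43e-11, adjusted p = 0.271 with an estimated correlation). With depth class as a term the medians of ribosome biogenesis and ribosomal proteins were 0.73 and -0.33, and with quantile normalization 0.73 and -0.04.

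Of 37 TCA cycle and respiration genes 9 fell and none rose (9 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.655 with an estimated correlation), with LSC2 at -2.15, ACO1 at -1.69, FUM1 at -1.64 and SDH3 at -1.47. The median of this list was -0.31, or -0.35 with depth class as a term. That of the stress response list was -0.59, or -0.44 with that term. Of 18 glycolysis and fermentation genes 5 fell (5 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.271 with an estimated correlation). Among them were ALD4 and the gluconeogenic enzymes FBP1 (-2.43) and PCK1 (-1.59). Of 6 galactose and lactose genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.461 with an estimated correlation): GAL10 (-1.80), GAL7 (-1.54) and GAL1 (-1.34). In the stress response list 8 of 22 genes fell and 3 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.142), with falls of HSP12 (-2.34), the glycogen phosphorylase GPH1 (-2.10) and CTT1 (-1.24, -0.91 and not called without WT replicate 2). Other falls were TMA17 (-2.58), SPG4 (-2.42), MDM36 (-2.21), GUT2 (-2.18), the invertase gene SUC2 (-2.00, 1 of 2 genes found of the sugar transport list) and the permeases PTR2 (-1.98) and PUT4 (-1.12, -0.94 and not called without WT replicate 1; 2 of 17 amino acid uptake genes).

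The cell wall list was lower (median -0.34, camera adjusted p = 0.0339, adjusted p = 0.421 with an estimated correlation) and the multidrug export list higher (median 0.54, camera adjusted p = 0.0339, adjusted p = 0.271 with an estimated correlation), both with no gene called. DTR1 missed the fold threshold (0.98) and passed it without WT replicate 1 (1.11) or sum1∆ replicate 1 (1.05). Among 47 amino acid synthesis genes 2 rose, MET14 (3.25) and MET16 (1.19), and 2 fell, MET5 (-1.16) and MET17 (-1.02). The MET5 and MET17 calls were lost without WT replicate 2 (-0.99 and -0.89), and that of MET17 with a pseudocount of 5 (-0.96). FET4 (1.11) and FRE1 (1.07) rose among 13 iron genes, and the FRE1 call was lost without WT replicate 2 (0.88) and that of FET4 with a pseudocount of 5 (0.97) or quantile normalization (0.93). SPL2 rose (1.67, 1 of 7 phosphate genes), as did PHO92 (4.41), CTS2 (4.31), KLLA0F24596g (7.10) and KLLA0C17226g (7.09). KLLA0B09064g and KLLA0C18117g fell by 4.35 and 3.62. Of 10 selectable markers 1 fell, MET5, and no histone gene was called. Among 10 silencing factors SUM1 was the 1 call, and the median of 0.20 and mean of -0.23 differed in sign. Camera gave adjusted p between 0.0879 and 0.939 for the lists on silencing factors, iron, phosphate, amino acid uptake and synthesis, selectable markers and histones.

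**Figure D2:**
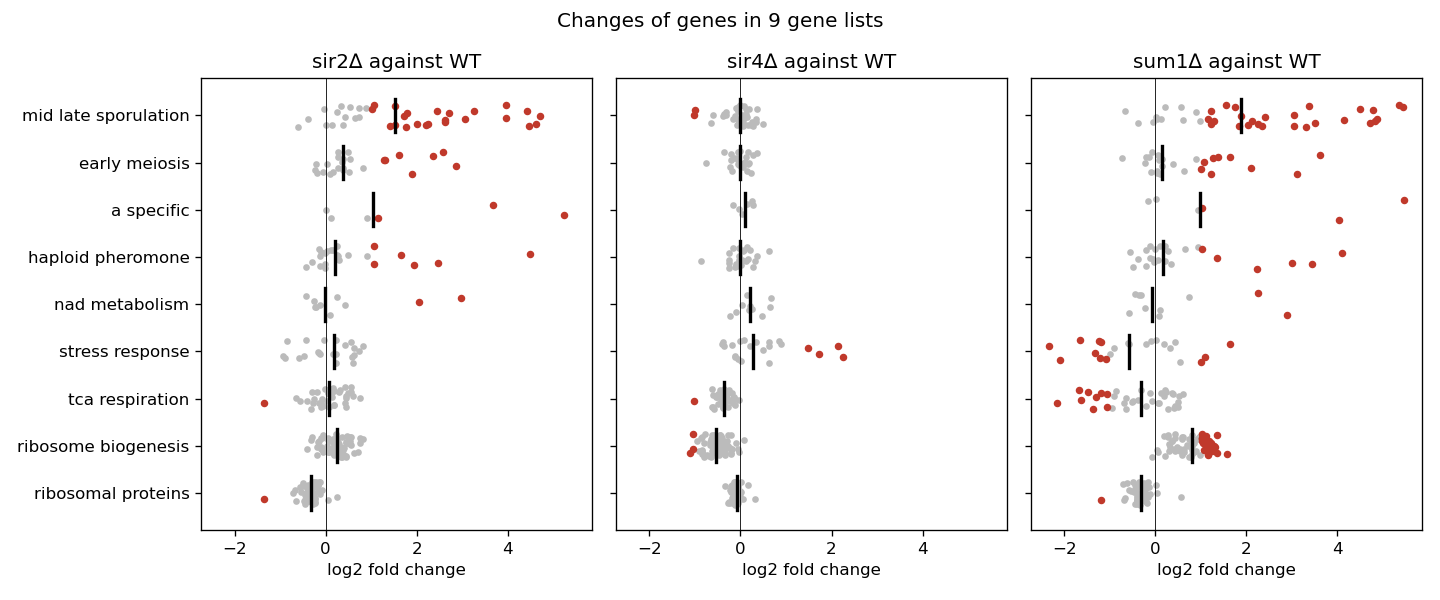
Log2 fold changes against WT (horizontal axis) of the genes of 9 lists (rows) in sir2∆, sir4∆ and sum1∆, with called genes in red, other genes in grey and a black bar at the list median. The middle and late sporulation medians are 1.53 in sir2∆, -0.01 in sir4∆ and 1.89 in sum1∆, and the ribosome biogenesis medians are 0.24, -0.54 and 0.81.

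The lists of called genes were compared between mutants. In sir2∆ and sum1∆ 206 genes were higher than WT in both, 83.7% of the 246 and 53.1% of the 388, and 25 were lower in both. Independent lists would share 19.0 and 1.03 genes. Simulated unchanged groups sharing the WT libraries had on average 0 and 0.01 genes higher and lower in both, and at most 0 and 1. Unchanged groups give few calls at these thresholds (0 of 4822 unchanged genes in the simulated test of the model), so the simulated overlaps could hardly be large. They do not decide whether noise of the shared WT libraries adds to the overlap. A difference common to both WT libraries is not covered by the simulations. Across genes, which are not independent replicates, the fold changes of sir2∆ and sum1∆ had r = 0.86 (0.49 on average in simulations of unchanged groups sharing the WT libraries), and a covariance of 0.477 against a simulated 0.00443. Fewer genes were shared with sir4∆. For sir2∆ and sir4∆, 4 genes were higher in both and 0 lower in both, against 1.52 and 0.265 for independent lists, with r = -0.18 (0.49 in the simulations). For sir4∆ and sum1∆, 3 were higher and 9 lower in both, against 2.40 and 1.06, with r = -0.21 (0.50 in the simulations). Of the sir4∆ rises, 7 were falls in sum1∆, and of the sir4∆ falls, 9 were rises in sum1∆, against 0.889 and 2.86 for independent lists. Of the sir2∆ rises, 8 were falls in sir4∆, and of the sir2∆ falls, 4 were rises in sir4∆, against 1.81 and 0.222. Between sir2∆ and sum1∆, 4 sir2∆ rises were falls in sum1∆ and 0 sir2∆ falls were rises there, against 7.05 and 2.78. Leaving out 1 library at a time, the genes higher and lower in both ranged over 1 to 6 and 4 to 13 for sir4∆ and sum1∆, 1 to 9 and 0 to 2 for sir2∆ and sir4∆, and 200 to 216 and 21 to 38 for sir2∆ and sum1∆. With quantile normalization the last pair shared 157 and 45. The simulated covariances of these pairs were 0.00449 and 0.00457 and the observed ones -0.0409 and -0.0589.

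**Figure D3:**
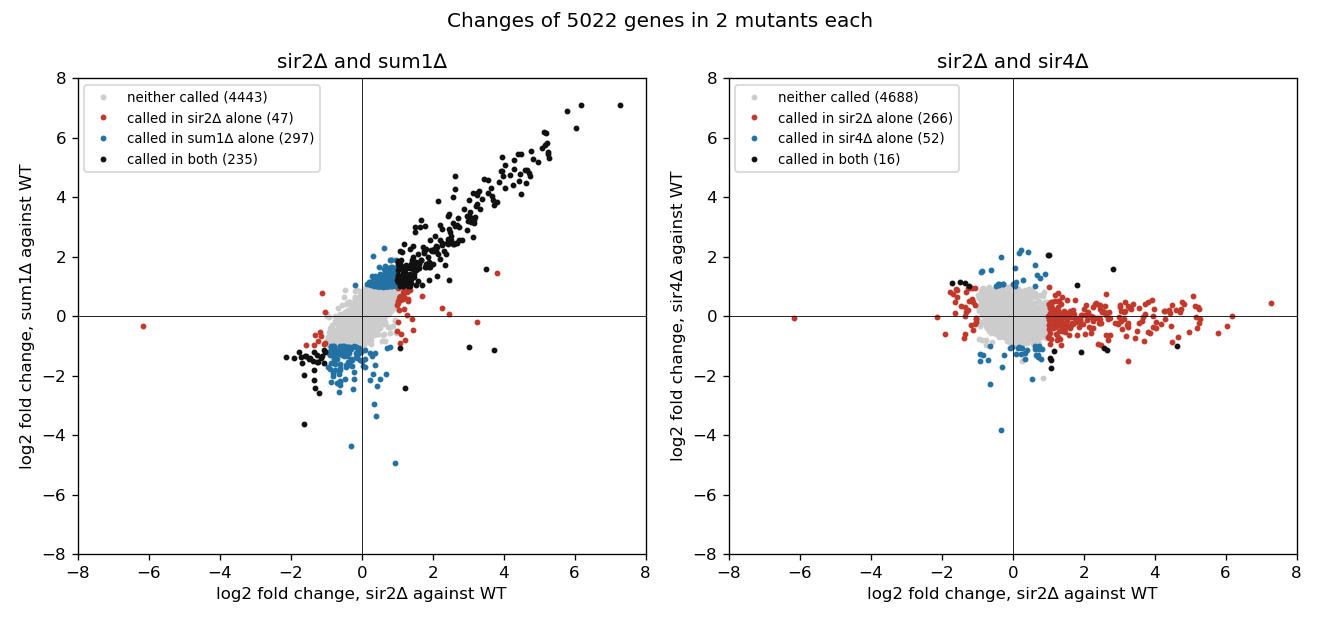
Log2 fold change against WT of 5022 genes in sir2∆ (horizontal axes) and in sum1∆ or sir4∆ (vertical axes), each point a gene, coloured by whether it was called in neither mutant, in the first alone, in the second alone or in both in any direction. The 206 genes higher in both sir2∆ and sum1∆ lie in the upper right, with r = 0.86 across all genes in that panel and r = -0.18 in the other.

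Direct comparisons of the mutants called 87 genes higher and 34 lower in sir2∆ than in sum1∆. Apart from SUM1, the genes with a symbol that were higher in sir2∆ by most were ALD4 (98.4 ± 17.2 against 6.23 ± 0.400 FPKM, log2 fold change 3.77, SE 0.11, adjusted p = 4.9e-07), HSP12 (2.78), FBP1 (2.19) and DPI8 (2.02). SPR3 (-2.09), SPO21 (-1.70), GIP1 (-1.41), KAR4 (-1.35) and GPR1 (-1.35) were lower in sir2∆ than in sum1∆. Of the 206 shared rises 19 were called stronger in sum1∆ and 2 stronger in sir2∆. Of the 182 genes called higher in sum1∆ and not in sir2∆, the direct comparison called 7, and of the 40 called in sir2∆ and not in sum1∆ it called 16. Of the 119 genes called lower in sum1∆ and not in sir2∆ it called 55, and of the 11 called lower in sir2∆ alone it called 3.

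Between sir2∆ and sir4∆, 439 genes were higher and 162 lower in sir2∆, 73.0% of calls being higher, against 60.6% with quantile normalization. Without the fold threshold the counts were 1808 and 1750. PFS1 (5.63), STE18 (5.35), AGA2 (4.98), RRT8 (4.78) and SSP2 (4.57) were higher in sir2∆. ERG1 (-2.81), STE23 (-2.58), SUR2 (-2.46), ERG11 (-2.45) and GRE3 (-2.38) were lower. Between sir4∆ and sum1∆, 246 genes were higher and 636 lower in sir4∆, 27.9% of calls being higher, against 38.2% with quantile normalization, which moved the median of all genes in this comparison from 0.01 to 0.12. Without the fold threshold the counts were 1865 and 1825. HSP12 (4.49), TMA17 (3.52), CTT1 (3.48) and OM45 (2.85) were higher in sir4∆ than in sum1∆. GIP1 (-5.72), PFS1 (-5.50), MUM3 (-5.26), AGA2 (-5.21) and RRT8 (-5.09) were lower. These mutants lie wholly in different depth classes.

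Genes near chromosome ends were compared with the rest, since Sir proteins act near telomeres in budding yeast. Of 84 tested end genes 15 were called higher in sir2∆ (17.9%, against 4.68% of 4938 other genes, odds ratio 4.43, Fisher's exact p = 1.04e-05). In sir4∆ 3 end genes were called higher (3.57% against 0.567%, odds ratio 6.49, Fisher's exact p = 0.0145), which did not pass with the outermost 5 or 20 genes per end (exact p = 0.17 and 0.119). Without sir4∆ replicate 2 the odds ratio was 3.94 (exact p = 0.0479). In sum1∆ 10 were called higher (11.9% against 7.65%, odds ratio 1.63, Fisher's exact p = 0.148), which passed with the outermost 5 genes (exact p = 0.0248) and without WT replicate 2 (exact p = 0.0291). Over all 12 such tests the adjusted exact p were 4.16e-05, 0.0249 and 0.197. The 12 include direct comparisons of mutants. Ends held more genes higher in sir4∆ than in sum1∆ (26.2% against 4.54%, odds ratio 7.47, adjusted exact p = 4.45e-10). They also did for sir2∆ over sum1∆ (16.7% against 1.48%, odds ratio 13.3, adjusted exact p = 5.38e-10). For sir2∆ over sir4∆ the shares were 21.4% and 8.53% (adjusted exact p = 0.000624). In the opposite directions the adjusted exact p were 0.446, 0.165 and 0.419. Of the 15 end genes higher in sir2∆, 7 were also higher in sum1∆, 3 were lower there and none was called higher in sir4∆, while 6 were called higher in sir2∆ than in sum1∆ directly. Genes are not independent, and neighbouring or duplicated genes can share reads.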

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

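The depth term and the sir4∆ control were chosen after seeing the data, and the other alternatives before. Counts of called genes stayed within 1.5 times under most settings, and those of sir4∆ moved further than that without WT replicate 1, WT replicate 2 or sir4∆ replicate 2. Of 1116 recomputed values of named genes that were called, 1084 kept the call, 32 lost it and 0 changed sign. Of 837 values of named genes that were not called, 832 stayed so, 5 gained a call and 29 changed sign. The cause of each change below was not tested unless the setting itself gives it.

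Without the fold threshold, which admits small changes by construction, the counts higher and lower were 1452 and 1465 in sir2∆, 842 and 1051 in sir4∆, 1689 and 1635 in sum1∆, 1808 and 1750 for sir2∆ against sir4∆, 839 and 1214 for sir2∆ against sum1∆, and 1865 and 1825 for sir4∆ against sum1∆. Overlaps higher and lower were then 136 and 189 for sir2∆ and sir4∆, 1133 and 1081 for sir2∆ and sum1∆, and 152 and 223 for sir4∆ and sum1∆. With limma's treat against a log2 fold of 1, a stricter test by construction, they were 148 and 11, 0 and 0, 199 and 65, 217 and 57, and 38 and 10, and sir4∆ against sum1∆ had 132 and 426. The 0 and 0 for sir4∆ compare with 16 and 13 at an unadjusted p below 0.05 in treat.

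Quantile normalization gave 90 genes lower in sir2∆, 2 higher in both sir2∆ and sir4∆, and 45 lower in both sir2∆ and sum1∆. A pseudocount of 0.1 gave 7 genes higher in both sir2∆ and sir4∆ and 5 in both sir4∆ and sum1∆, and a pseudocount of 5 gave 1 for sir2∆ and sir4∆. The depth term left 19 genes higher in sir4∆. With an estimated correlation 1, 0 and 1 lists passed in sir2∆, sir4∆ and sum1∆ (2, 1 and 2 at an unadjusted p below 0.05), against 5, 6 and 10 with the preset. With fry 15, 8 and 18 passed. With the outermost 5 and 20 genes the chromosome-end odds ratios were 8.60 and 2.89 in sir2∆ and 5.70 and 2.66 in sir4∆. In sum1∆ the odds ratio was 3.02 with the outermost 5. Replicate numbers did not pair the libraries (correlations of same-numbered deviations from -0.251 to 0.025), and the replicate block moved no count by over 1.5 times.

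Leaving out 1 library at a time assumes that a lone library varies like the other groups. The ranges were 236 to 256 higher and 32 to 53 lower in sir2∆, 17 to 70 and 20 to 64 in sir4∆, 343 to 429 and 127 to 150 in sum1∆, 402 to 492 and 137 to 186 for sir2∆ against sir4∆, 81 to 91 and 30 to 40 for sir2∆ against sum1∆, and 217 to 285 and 623 to 671 for sir4∆ against sum1∆. Overlaps ranged over 1 to 9 and 0 to 2 for sir2∆ and sir4∆, 200 to 216 and 21 to 38 for sir2∆ and sum1∆, and 1 to 6 and 4 to 13 for sir4∆ and sum1∆. List counts were 4 to 7, 4 to 7 and 10 to 11, and end odds ratios 3.54 to 5.08, 3.94 to 8.005 and 1.63 to 2.09 in sir2∆, sir4∆ and sum1∆. The upper end of the range of shared falls of sir2∆ and sum1∆ came without WT replicate 1. The highest end odds ratio in sum1∆ (2.09) came without WT replicate 2.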

Other observations

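The tests of depth class, of a state shared by replicates and of shared WT libraries were chosen only after the results they address were seen. The depth test was first made against WT replicate 2 alone and then replaced by the fit with a depth term. Predictions for neighbouring genes were written beforehand for 3 of the 6 sets tested, and the rule for reading their counts was loosened after the counts were seen.

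In sum1∆ and sir4∆ chromosome ends also held an excess of falls, which the planned comparison of rises did not cover. In sir2∆ 1 of 84 end genes fell (1.19% against 0.709%, odds ratio 1.69, Fisher's exact p = 0.456). In sum1∆ 11 of 84 end genes fell (13.1%, against 2.69% of other genes, odds ratio 5.44, Fisher's exact p = 2.27e-05, adjusted exact p = 6.81e-05 over 12 tests), and in sir4∆ 5 fell (5.95% against 0.648%, odds ratio 9.70, exact p = 0.000332, adjusted exact p = 0.000664). Of these 5 sir4∆ genes, 4 form a run of neighbouring genes without symbols, at places 7 to 10 from 1 chromosome end. They fell by 1.27 to 2.27 on the log2 scale, and 0 of them were called in sir2∆ or sum1∆. The exact test counts this 1 site as 4 separate genes, so the excess in sir4∆ rests mostly on 1 chromosome end.

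The sir4∆ effect ran along a difference between the WT libraries. Of the 68 genes called, 63 (92.6%) differed between WT replicate 2 and WT replicate 1 in the direction of the sir4∆ change, against 69.3% of all genes. The sir4∆ change was taken against the mean of these same WT libraries. A deviation of WT replicate 1 alone would therefore move both quantities the same way. This holds for the r of 0.501 below too, but not for the value in sir2∆, which uses other libraries. Depth class as the whole explanation is argued against by the fit with a depth term: the median change of the 68 genes, signed by direction, was 1.12 (quartiles 0.981 and 1.39), against 1.25 without the term and 1.06 against WT replicate 2 alone, and 45 of the 68 were still called. The other 23 fell below the thresholds. The lower quartile was 1.08 without the term, so it moved little but across the fold threshold of 1. Lost calls alone therefore do not show a depth effect, though depth class may account for part of the change. A growth or RNA state that also varies between replicates remains open: across genes the sir4∆ effect had r = 0.501 with the replicate difference in WT, -0.308 in sir2∆ and 0.042 in sum1∆, and taken as shallow minus deep both of the first values are positive (0.501 and 0.308), so such a state and depth class overlap. Loss of Sir4 stays open too and was not tested apart from these. Weaker correlations of opposite sign were seen for the other mutants. Shallow minus deep in WT had r = -0.191 with the sir2∆ effect and -0.191 with the sum1∆ effect. That in sir2∆ had r = -0.111 and -0.188, and of these values only -0.188 shares no library with the effect. A growth or RNA state was not tested apart from loss of Sir2 or Sum1 either.

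The shared rises of sir2∆ and sum1∆ are poorly explained by the shared WT libraries. With the sir4∆ libraries as the control of sum1∆, 197 genes were higher in both, against 31.2 for independent lists and 206 with WT as the control of both. With depth class as a term 207 were shared, which does not bear on the shared WT libraries. This term could change only the sum1∆ list, since WT and sir2∆ each hold both depth classes. Reads of neighbouring genes, which this kit cannot assign to a strand, were not tested as a cause.

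A hypothesis that genes called together lie next to each other was tested by counting adjacent pairs. Of the sets with a prediction, genes lower in sir4∆ formed 4 pairs against 0.269 at random (permutation p = 0.0002, adjusted p = 0.0006 over 6 sets), of which 3 lie in the run of 4 genes above. Genes higher in sum1∆ formed 38 pairs against 29.8 at random (permutation p = 0.07, adjusted p = 0.11), and genes higher in sir4∆ formed 1 pair against 0.185 (permutation p = 0.2, adjusted p = 0.24); both predictions required more pairs than the upper random limits of 40 and 1, which were not exceeded, so by the rule as first written both predictions failed. Under the rule loosened afterwards, counts inside the random range leave the question open. Of the sets without a prediction, genes higher in sir2∆ formed 26 pairs against 11.9 (permutation p = 0.0003, adjusted p = 0.0006), genes lower in sum1∆ formed 16 against 4.08 (permutation p = 0.0001, the smallest these permutations can give, adjusted p = 0.0006) and genes lower in sir2∆ formed 0 against 0.247 (permutation p = 1). Shared regulation and reads crossing between neighbours cannot be separated without strand.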
